A study of Mus musculus with 4 samples.

How the data were processed

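Copy number was measured on 4 arrays of one Agilent design (027411, positions on mm9), 2 of phESC and 2 of C57BL/6 liver, each against a liver reference. Groups and replicate numbers came from the sample titles. Only the phESC samples are described as biological replicates in the labels, so the p-values measure the spread between these arrays, which may in part be technical. All 4 arrays lay on 1 slide and were scanned together, phESC on positions 1 and 2 and liver on positions 3 and 4. Position on the slide and group therefore cannot be told apart.

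Per the file headers, the authors extracted the images with Agilent Feature Extraction 11.0.1.1, which gave background-subtracted intensity values per channel. Per the file headers, the dyes were normalised by 1 linear factor per channel, with no lowess term. The authors' deposited value table is the log10 ratio of red (Cy5) over green (Cy3), since it equalled the scanner files' log10 ratio at each of the 180880 spots of every array. The medians of its columns were -0.00347, -0.00048, 0.00289 and -0.00088 for phESC replicates 1 and 2 and liver replicates 1 and 2. It is not centred further. The columns of flags per spot, deposited by the authors, are of 0 and 1.

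From the processed intensities, log2(Cy3/Cy5) was computed per spot and centred on each array's median over autosomal probes, with no loess or quantile step. Control spots (6575) and spots with an outlier flag were left out. Of 170305 distinct probes, 1000 were spotted 5 times and were averaged, and 170216 entered the tests. Probes, means of 1 Mb windows with at least 10 probes, and medians of chromosomes were compared between phESC and liver with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. All tests were two-sided. Segments were found per array by a recursive search for the interval with the highest score, the sum of log2 ratios over the robust SD times the square root of the number of probes, in the manner of ADM-2. A segment needed a score of at least 6, at least 3 probes and an absolute mean of at least 0.25. Shared segments overlapped by at least 50% of each, with the same sign, and met no liver segment of that sign. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0, scipy 1.17.1 and matplotlib 3.10.9 was used.

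The procedures were tested on simulated data, with noise set from the scatter between neighbouring probes of each array. Of 200 changed windows among 2534, each of those changed by 0.25, 0.58 or 1 was recovered (100% of each size), with 4 unchanged windows called. Of 200 changed probes among 170216, 0% of those changed by 0.25 were recovered, 14.9% at 0.58 and 95.5% at 1. Of 20 planted segments of 3 probes at 0.58, the search found 35% with the noise of phESC replicate 1 and 75% with that of phESC replicate 2. All planted segments of 8 or 15 probes were found on these arrays. The simulated noise was independent between probes and between arrays, which real arrays need not follow. The phESC replicates shared much of their scatter and differed with an SD of 0.13 over probes. The simulated spread between phESC arrays was thus larger than in the data, so the recovery of probes does not describe these arrays. In the data a far larger share passed (26.01% of probes and 80.07% of windows) than was changed in the simulation. The adjusted threshold was therefore stricter in the simulation, and its recovery shares need not hold for the data.

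Comparisons, named items and alternatives were fixed before the data were examined, except where stated. Named were each chromosome past 0.05 and chromosomes 1, 8, 11, X and Y, the 5 highest and 5 lowest windows past 0.05, and the 10 shared segments with the highest absolute mean. The plan also named genes and gene lists. The files pair no probe with a gene, and the gene table given is on another build, so gene and gene list tests, and GC corrections, were not run. Alternatives were normexp background correction, the authors' table, other centring, filters on dim or flagged spots, loess within arrays, each array left out, the replicate number as a block, other window sizes, summaries and segment thresholds. The normexp alternative used the median spot signals. The turned dyes, the crossed block and the removal of a probe density trend were added after the data had been seen. That removal subtracted a loess fit on probes per window from each array, which also took off the array's overall level over windows.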

Results

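Genomic DNA of 2 biological replicates of mouse parthenogenetic haploid embryonic stem cells (phESC) and of 2 C57BL/6 liver samples was hybridised to 4 two-colour comparative genomic hybridisation arrays. Parthenogenetic haploid cells derive from activated eggs and carry a single set of maternal chromosomes. Per the labels, each sample was in the Cy3 channel and a liver reference DNA was in the Cy5 channel of every array. The liver arrays therefore compare liver with liver and give the background of the method. Each array held 174305 non-control spots, with probes of 45 to 60 bases (median 60) at a median spacing of 10878 bases, on the mm9 build. At least 99.9% of these spots were well above background in either channel. The scatter between neighbouring probes had an SD of 0.188 and 0.147 (log2) on phESC replicates 1 and 2, and of 0.111 and 0.104 on liver replicates 1 and 2. On the phESC arrays much of it was common to both replicates, so it is not noise alone. The phESC replicates differed from each other with an SD of 0.13 over probes (r = 0.88), and the liver replicates with an SD of 0.16 (r = 0.13).

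All signed values below are log2(Cy3/Cy5), which by the labels is sample over reference, but this direction was not settled by the data. Across probes, the log2 signals of 6 of the 8 channels, among them both Cy3 channels of the phESC arrays, correlated with each other at r = 0.989 to 0.996. The Cy5 channels of the phESC arrays correlated with those 6 at only r = 0.958 to 0.975, and with each other at r = 0.992. Probes are not independent replicates. In all 44 segments that both phESC arrays shared, the Cy5 signal differed more between phESC and liver arrays than the Cy3 signal did. Chromosome X and the strongest shared segment are therefore also described by channel, and values with the sign of the phESC arrays turned are given with the alternatives.

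The first comparison asked whether whole chromosomes had been gained or lost in phESC. No autosome differed by an amount near a whole copy in all cells. An extra copy would be 1.0 on the log2 scale in a haploid set and 0.58 in a diploid set, whereas the largest autosomal difference between phESC and liver was -0.0877 ± 0.0046 (SE, n = 2 arrays per group), on chromosome 11. The 95% confidence intervals of all 19 autosomes reached at most 0.1013 from 0 in either direction, and at most 0.116 with the sign of the phESC arrays turned. Chromosomes 1 and 8, often gained in cultured mouse embryonic stem cells as chromosome 11 also is, differed by 0.0353 (95% confidence interval 0.0261 to 0.0446) and by 0.0053 (interval -0.00064 to 0.011). A ratio against the median of each array cannot show the number of whole chromosome sets.

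Small shifts were reproducible between the replicates, and 18 of 21 chromosomes differed between phESC and liver at a Benjamini-Hochberg adjusted p under 0.05 in limma. Of these, 10 were higher and 8 lower, whereas with the sign of the phESC arrays turned 19 passed, 8 higher and 11 lower. Besides chromosome X, chromosome 3 (0.0541), chromosome 1 (0.0353), chromosomes 6, 16 and 14 (0.0308, 0.0306 and 0.0306), chromosomes 18 and 13 (0.0189 and 0.0153), chromosome 10 (0.0128) and chromosome 12 (0.0094) were higher. Chromosome 11 (-0.0877), chromosome 19 (-0.0474), chromosomes 17, 9, 5 and 7 (-0.0255, -0.0251, -0.0237 and -0.0228), chromosome 4 (-0.0133) and chromosome 2 (-0.0105) were lower. The adjusted p of these autosomes was at most 0.0127 in limma. Chromosome 8 (adjusted p = 0.0744 in limma), chromosome 15 (adjusted p = 0.445) and chromosome Y did not pass, although chromosome 8 passed with loess (adjusted p = 0.0204) and with the replicate number as a block (adjusted p = 0.0471). The moderated variance was estimated from 21 chromosomes only, and 4 passed with means of probes in place of medians. In that fit all chromosomes shared 1 SE of 0.0169, against 0.0032 for chromosome 1 in the main fit. Without liver replicate 1 or 2 all shared an SE of 0.0125, while chromosome 1 was at 0.0388 and 0.0318. Chromosome Y entered the shared spread, with a phESC SD of 0.0455 against 0.0012 on chromosome 1.

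**Figure D1:**
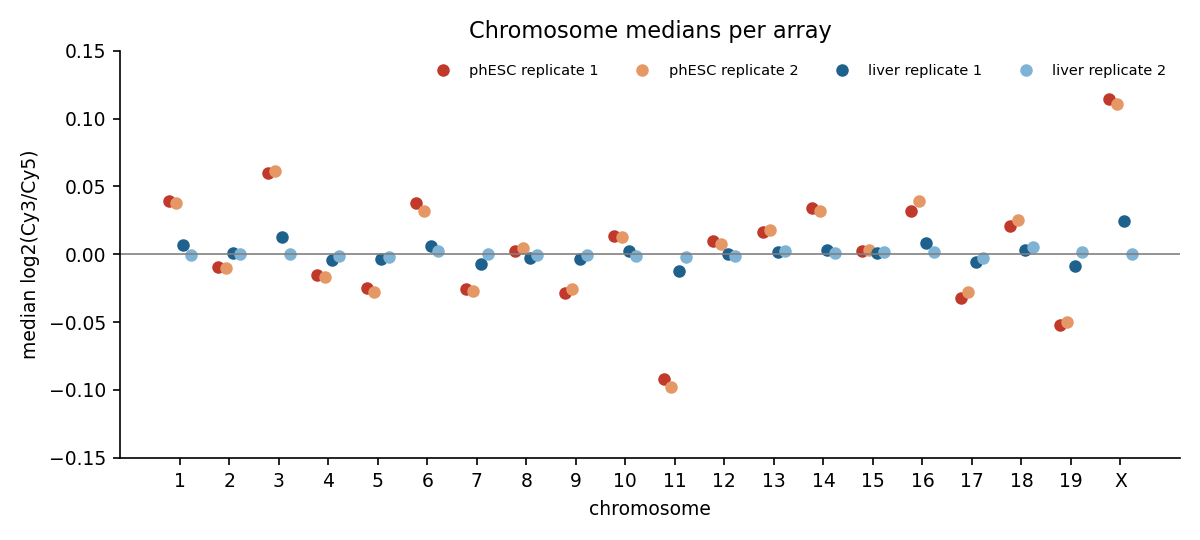
Median log2(Cy3/Cy5) of the probes of each autosome and chromosome X (vertical axis) by chromosome (horizontal axis), 1 point per array, for 2 phESC and 2 liver arrays. The phESC points of chromosome X lie at 0.114 and 0.111 and those of chromosome 11 at -0.092 and -0.098, whereas the liver points of chromosome X lie at 0.025 and 0.0003.

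The sex chromosomes were compared because parthenogenetic cells hold no paternal genome. The log2(Cy3/Cy5) of chromosome X was higher on the phESC than on the liver arrays by 0.10 ± 0.0094 (SE, n = 2 per group, 95% confidence interval 0.07 to 0.13, adjusted p = 0.00212 in limma), with 8713 probes. Both phESC arrays lay above both liver arrays, but by far less than the 0.58 or 1.0 of an extra copy in all cells. The difference became -0.13 with the sign of the phESC arrays turned. Its mean over windows fell from 0.11 to 0.046 once a trend with probe density was removed. Both alternatives were chosen after the data had been seen. The removal also took off each array's overall level over windows, so this fall does not measure density alone. On X, 94 of the 148 windows of 1 Mb were higher and 25 lower, against 24 higher and 100 lower with the sign turned, and 78 higher and 42 lower after removal of the density trend. By channel, the median X signal in Cy5 was 915 and 916 on phESC replicates 1 and 2, against autosomal medians of 992 and 998. On liver replicates 1 and 2 it was 991 and 999, against 1026 and 1022. In Cy3 it was 986 and 989 (autosomal 1000 and 1007) on the phESC arrays and 1002 and 998 (1019 and 1027) on the liver arrays. The shift of X thus lay mainly in Cy5, by the labels the reference channel. Chromosome Y gave no fold, because its signal was near background in every channel. The median Y signal was 48.5 to 53.7 intensity units, which is 4.72% to 5.38% of the autosomal median of the same channel. Of 134 Y spots, 47 were well above background in all 8 channels and 52 in none. The 122 Y probes differed by -0.02 (95% confidence interval -0.12 to 0.08, adjusted p = 0.576 in limma). This call was not stable: Y passed at 0.0695 with only probes well above background in the reference channel (adjusted p = 0.00284 in limma), at -0.0918 with means of probes (adjusted p = 5.26e-05) and at -0.0514 without liver replicate 1 (adjusted p = 0.00206).

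The second comparison asked where along the chromosomes the phESC arrays departed from liver. Both phESC arrays showed the same alternation of higher and lower domains, a few Mb wide, along all chromosomes. In limma, 2029 of 2534 windows of 1 Mb differed (adjusted p under 0.05), 1110 higher and 919 lower. The majority reversed to 929 higher and 1191 lower with the sign of the phESC arrays turned, and to 910 higher and 1024 lower after removal of the density trend. That removal also took off each array's overall level, and the median window difference went from 0.0161 to -0.0115. The second reversal therefore does not show an effect of density by itself. Most of the 2029 differences were small, and 294 windows differed by at least 0.25, 277 of them higher and 17 lower. That count was 525 (74 higher, 451 lower) with the sign of the phESC arrays turned, 564 (458 higher, 106 lower) with normexp, 172 without liver replicate 2 and 122 (87 higher, 35 lower) after removal of the density trend. In 91.7% of the windows both phESC arrays lay on the same side of both liver arrays, against 33.3% by chance. Runs of adjacent windows past the threshold with the same sign reached 19 Mb, as on chromosome 16 (65000001 to 84000000, higher, 1 of 2 runs of this length), and 16 Mb on chromosome 17 (21000001 to 37000000, lower). With the sign turned these became 19 Mb lower and 15 Mb higher, the latter from 22000001. After removal of the density trend other runs were longest, 11 Mb higher on chromosome 14 (88000001 to 99000000) and 32 Mb lower on chromosome 4 (118000001 to 150000000).

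The highest window was 53000001 to 54000000 of chromosome 14, at 0.68 ± 0.03 (SE, adjusted p = 0.000283 in limma). This value came from part of its 26 probes, since the window's median difference was 0.01 (adjusted p = 0.619 in limma). Next were the windows that start at 150000001 on chromosome 1 (0.41), 98000001 on chromosome 2 (0.41), 79000001 on chromosome 5 (0.38) and 117000001 on chromosome X (0.38). The lowest was the window from 66000001 on chromosome 17, at -0.33 ± 0.03 (SE, adjusted p = 0.00046 in limma). It was followed by those from 21000001 on chromosome 12 (-0.29), 132000001 on chromosome 4 (-0.28), 146000001 on chromosome 4 (-0.28, 12 probes) and 127000001 on chromosome 10 (-0.27). In these 10 windows both phESC arrays lay on the same side of both liver arrays. These ranks depended on the processing: with normexp the chromosome 14 window fell to 0.37, below those of chromosomes 1 (0.50) and 2 (0.54), and with the sign turned the chromosome 4 window from 146000001 (0.34) passed that of chromosome 17 (0.33). After removal of the density trend the windows of chromosomes 1, 2, 5 and 10 shrank to 0.22, 0.25, 0.18 and -0.18, while those from 146000001 on chromosome 4 (-0.55) and of chromosome 12 (-0.45) lay below that of chromosome 17 (-0.29).

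**Figure D2:**
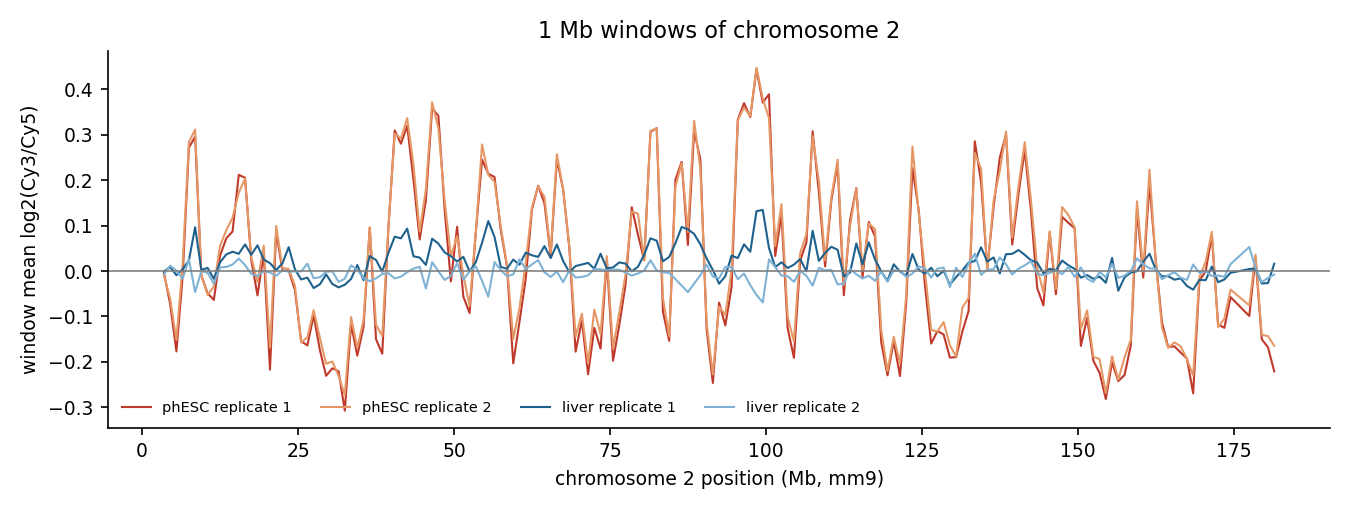
Mean log2(Cy3/Cy5) of 1 Mb windows (vertical axis) along chromosome 2 (horizontal axis, Mb on mm9), 1 line per array. The 2 phESC lines run together and peak at 0.445 and 0.447 in the window from 98000001, where the liver lines are at 0.132 and -0.053.

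Of single probes, 44279 of 170216 differed (23382 higher, 20897 lower, limma adjusted p under 0.05), 40979 of them by at least 0.25. With the sign of the phESC arrays turned 69882 differed, 33192 higher and 36690 lower. Liver replicates 1 and 2 differed from each other with an SD of 0.158 over probes. The probe count was 22 without phESC replicate 1 and 16167 (6311 higher, 9856 lower) without phESC replicate 2. Each of these fits had a single phESC array and took its spread from the liver pair alone, so the drop does not show what the count rested on.

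The third comparison asked for intervals gained or lost in phESC. The search found 72 segments on phESC replicate 1 and 69 on phESC replicate 2, against 5 on each liver array. Of these, 44 were called on both phESC arrays and on neither liver array, 30 with Cy5 below Cy3 and 14 with Cy5 above Cy3. Their median length was 2.1 Mb, and 29 were at least 1 Mb long. Segments with an absolute mean of at least 0.5 numbered 7 and 6 on the phESC arrays, 3 of them shared, and 0 on the liver arrays.

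The strongest shared segment lay on chromosome 14, from 53344319 to 54291286 (947 kb, 15 probes). There the Cy5 signal of the phESC arrays was far below the Cy3 signal, with a log2(Cy3/Cy5) of 3.24 ± 0.04 (SD, n = 2). All 15 probes went the same way on both arrays, and 14 exceeded 1.0 on both. The liver arrays were at -0.04 ± 0.05 (SD, n = 2). By channel, Cy5 was -3.21 on the log2 scale on phESC against liver arrays, and Cy3 was 0.06. In Cy5 of both phESC arrays, 3 of the 15 probes were not well above background, so no fold is given. The value was 2.92 over the 12 probes well above background and 2.04 with normexp. The first probe beyond the right edge, at 54320774, was near the autosomal median on phESC replicates 1 and 2 (Cy3 -0.028 and 0.005, Cy5 -0.106 and -0.1). The 2 probes after it, at 54344555 (0.87 and 0.79) and 54369708 (1.05 and 1.08), were raised on both. Raised probes were thus not confined to the segment. The other 18 of 20 flanking probes had means over both phESC arrays between -0.46 and 0.30. The 14 gaps between the starts of the segment's probes averaged 67.6 kb and ranged from 0.888 to 373.4 kb. Genes in the interval were not annotated here, so whether it holds a locus that is rearranged in some cells or varies between strains was not examined.

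**Figure D3:**
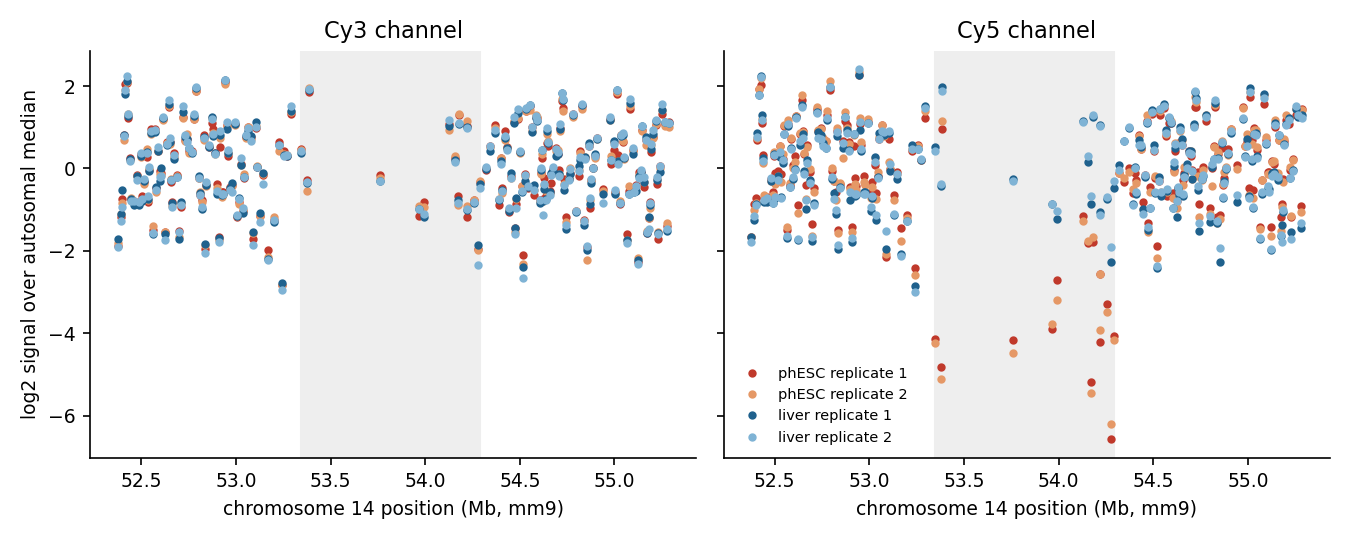
Log2 signal over the autosomal median (vertical axis) of probes on chromosome 14 (horizontal axis, Mb on mm9) in the Cy3 channel (left) and the Cy5 channel (right), 1 point per probe and array, with the shared segment shaded. Within it the phESC arrays average -0.09 in Cy3 and -3.32 in Cy5, and the liver arrays -0.15 and -0.11.

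The second strongest was a 62.8 kb segment of chromosome 1, from 129973740 to 130036549, with 8 probes. Its log2(Cy3/Cy5) was -1.07 ± 0.0012 (SD, n = 2) in phESC and 0.02 ± 0.0017 in liver. Cy5 was thus 2.1-fold above Cy3 on the phESC arrays. A 31.2 kb segment of chromosome 13 (76867029 to 76898205, 4 probes) was at -0.66 ± 0.01 in phESC and 0.08 ± 0.0081 in liver. A 19.9 kb segment of chromosome 1 (141366534 to 141386460) rested on 3 probes and was less even, at -0.61 ± 0.11 (SD, n = 2). With normexp it was -0.23, which is under the 0.25 needed for a call. A 78.1 kb segment of chromosome 1 (90115633 to 90193738, 10 probes) was at 0.44 ± 0.02.

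The other named segments were wider and shallower. They were 94861946 to 101137154 of chromosome 2 (0.37), 65975199 to 66853550 of chromosome 17 (-0.36, 78 probes), 98892605 to 105223602 of chromosome 8 (0.34), 13852477 to 16145990 of chromosome X (0.34) and 73678871 to 81646471 of chromosome 6 (0.31). On the chromosome 17 segment the replicates differed most among these, at -0.41 and -0.30. The remaining 34 shared segments had absolute means of 0.26 to 0.31. These are close to the 0.25 needed for a call and under the 0.58 or 1.0 of an extra copy in all cells. The search did not separate such segments from the broad domains, and no density trend was removed before it. The segment of chromosome 2 from 94861946, for example, holds the window from 98000001. Segments were called per array without a test between groups.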

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

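The tests of the channels and of the broad domains were chosen after their results had been seen, as were those of the chromosome 17 segment except the step at its edges.

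The Cy5 channel was taken singly and not as a ratio. Over the chromosome 14 interval it was lower on the phESC than on the liver arrays by a wide margin, at -3.21 (log2). There 3 of the 15 probes were not well above background in Cy5 of both phESC arrays, so the size of this difference is uncertain. Over the 44 shared segments the median absolute difference between phESC and liver arrays was 0.25 in Cy5 and 0.0225 in Cy3. The Cy5 value argues against phESC DNA in Cy3 with the same reference DNA in Cy5 on all 4 arrays. Dyes exchanged on the phESC arrays would give both values, and then the chromosome 14 interval may be a loss and the chromosome 1 interval a gain in phESC. A different reference DNA in Cy5 of the phESC arrays would give them too, but only if phESC DNA in Cy3 hardly differed from liver DNA. Under that condition it cannot be told apart from exchanged dyes, because under both the Cy3 channels would be alike. The Cy3 difference between the means of the 2 phESC and the 2 liver arrays had an SD over windows of 0.0206. That between the single Cy3 channels of liver replicates 1 and 2 was 0.0219. Single arrays carry more noise than means, so these values do not show that the Cy3 difference was noise alone.

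The broad domains were shared by the phESC arrays (r = 0.994 over windows). They were absent from liver replicate 2 (slope 0.00087, r = 0.016 and -0.0037 with phESC replicates 1 and 2). On liver replicate 1 they appeared at low amplitude but with the same pattern (slope 0.15, r = 0.74 and 0.76). If phESC DNA mixed into Cy5 of liver replicate 1 gave that slope, the chromosome 14 interval there should be higher than observed by 0.21 (SE of the 15 probes 0.0377), which argues against mixing. An intensity-dependent dye effect as the whole cause is also argued against, since the window differences kept a slope of 1.02 after loess. Sequence composition, with probe density in its place, stays open: removing the density trend left 0.80 of the SD. DNA replication in dividing phESC could raise probe-dense windows only if phESC DNA was in Cy5 (Spearman rho 0.59 for Cy5 over Cy3 across windows; by the labels it is -0.59, the opposite sign), and composition predicts a trend too, so the 2 cannot be told apart without sequence or replication data.

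The chromosome 17 segment differed between the phESC replicates by -0.10 (SE over 78 probes 0.016). Noise of the probes, each on its own, is argued against: the 40 flanking probes, which were not picked, differed by -0.0857 (SE 0.0211), or -3.28 SE from the median of 178 other low windows. A copy number change of this segment alone, in a different share of each replicate (a loss by the labels, a gain if the dyes were exchanged), is argued against, because that difference of the flanks lies within 2 SE of the segment's. Such a change reaching past the segment stays open: the flanks lay 0.24 from the segment's mean, but the search sets edges where the mean steps, so that step could hardly have been absent. A larger wave on replicate 1 stays open too, because the segment was picked for its difference, so that its lying beyond the range of the low windows (down to -0.0678) excludes nothing, and 4 of all 2534 windows, 2 of them on chromosome Y, differed more in size than the window from 66000001 that overlaps it (-0.0996).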

How the results depend on the processing

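The turned dyes, the crossed pairing, the removal of the density trend and the means of single phESC arrays for segments were chosen after the data had been seen; the other alternatives were planned. Probes past the threshold numbered 44279, and 22 to 43242 with 1 array left out (22 without phESC replicate 1, 16167 without phESC replicate 2), 69882 with the dyes of the phESC arrays turned. Windows numbered 2029, 1634 to 2086 with 1 array left out, 4014 of 5033 at 0.5 Mb and 422 of 531 at 5 Mb, where the number of windows itself differs. Chromosomes numbered 18, 4 to 15 with 1 array left out (9 without liver replicate 1, 4 without liver replicate 2) and 4 with means of probes. With the replicate number as a block, which the labels do not show to pair arrays, 30605 probes, 1915 windows and 19 chromosomes passed; deviations of same-numbered arrays correlated at -0.36 over probes and -0.03 over windows, and the crossed replicate block gave 69091 probes, 2076 windows and 19 chromosomes. Segments of phESC replicates 1 and 2, liver replicates 1 and 2, and shared, numbered 72, 69, 5, 5 and 44; they were 333, 362, 8, 6 and 261 at a mean of at least 0.15, 7, 6, 0, 0 and 3 at 0.5, and 176, 133, 2, 2 and 108 with normexp. Liver segments were 12 and 16 at a score of 5, 1 and 1 at a score of 8, and 2 on liver replicate 2 with the reference channel well above background. The X difference was 0.0879 to 0.112 with 1 array left out and reversed to -0.13 with turned dyes. The Y difference, near background, had no stable sign: 0.0695 with the reference channel well above background, 0.16 with loess, -0.21 with turned dyes, -0.0918 with means of probes, -0.0207 with the crossed block (past the threshold, as with the reference channel filter, turned dyes, means of probes and without liver replicate 1), and -0.0529 to 0.0115 with 1 array left out (above 0 without phESC replicate 2 and, at 0.0101, without liver replicate 2). Turning the phESC arrays alone reversed X and every named autosome, window and segment, but not Y. Chromosomes 1 to 14 in order became -0.0415, 0.0093, -0.0672, 0.0187, 0.029, -0.0388, 0.0299, -0.0018, 0.0291, -0.013, 0.10, -0.0083, -0.019 and -0.0352, and 16 to 19 became -0.0403, 0.0345, -0.0273 and 0.0543. The windows in the order of the text became -0.67, -0.47, -0.49, -0.44, -0.45, 0.33, 0.26, 0.29, 0.34 and 0.33, and the segments -3.24, 1.07, 0.66, 0.61, -0.44, -0.37, 0.36, -0.34, -0.34 and -0.31. Apart from turned dyes, no named autosome, window or segment changed sign; 47 of 234 values of autosomes and 1 of 140 of windows (chromosome 14, median of probes) no longer passed, and chromosome 8 newly passed with loess and with the block. With normexp the chromosome 14 segment was 2.04 (2.92 with the reference channel well above background) and the 3-probe chromosome 1 segment -0.23. Causes of this dependence on the processing were not tested. For chromosomes, the fits without 1 liver array and with means of probes gave all chromosomes the same SE (0.0125 and 0.0169). That is above the main SE of X (0.0094), so fewer calls there need not mean smaller differences. Gene, gene list and GC alternatives were not run. Signal over background limited chromosome Y and 3 probes of the chromosome 14 segment.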

Other observations

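The test in this part was chosen after the windows had been seen. The domains followed local probe density in part, since 0.80 of the SD over windows was left after removal of its trend. In the 514 windows with 10 to 44 probes the difference between phESC and liver averaged 0.19 (SD over windows 0.13), and in the 467 windows with 90 to 112 probes it averaged -0.0887 (SD 0.13). Windows with 45 to 63, 64 to 77 and 78 to 89 probes averaged 0.0721, 0.0075 and -0.0325. The correlation of the difference between windows was 0.59 at a distance of 1 Mb, 0.34 at 2 Mb and 0.13 at 5 Mb. Windows are not independent replicates.

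Chromosome X had a median of 59.5 probes per window against 70 on the autosomes. Its mean window difference was 0.11, and 0.046 after removal of the density trend. The mean window difference of chromosome 11 was -0.05 before and -0.0472 after that removal. Because the removal also took off each array's overall level over windows, these values do not isolate the effect of density on either chromosome.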
